A study of Homo sapiens with 17 samples.

How the data were processed

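Nuclei of Nthy-ORI cells were profiled by CUT&RUN with antibodies to TRβ, BRG1, ARID1A and PBRM1 after vehicle or 10 nM T3, with 500000 cells per reaction per the labels' protocols. The 17 libraries comprised 2 for each of 8 groups and 1 IgG library, which was not used here. Nothing in the labels says that replicates came from separate cultures, so agreement between them may be technical. The submitters' processing notes name CASAVA 1.7, Trim Galore, Bowtie2, MACS2 and the build hg38, without parameters; whether the IgG library served as a control, and the read depth, are not given in the sources used here.

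Each group had 1 deposited list of peaks found in both libraries, in the layout written by the IDR method, which models how well 2 replicates agree in the ranking of peaks. The authors' signal value of a peak is the sum of the values of its 2 libraries, and was used only to rank and describe peaks within a list. The deposited score is a scaled form of the irreproducible discovery rate, and the −log10 of that rate is a deposited column from which the lists were found to hold rates up to 0.05. The interval of a peak is the union of its intervals in the 2 libraries. Which column belongs to which numbered replicate is not stated, and 16 columns with a summit per replicate were not used. Because 1 list stood for each group, no test compared conditions across replicates.

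Peaks on chromosomes 1 to 22, X and Y were used, and overlapping peaks of a list were to be merged, of which there were 0. A region was shared if at least 1 bp overlapped a region of the other list, and otherwise T3-only or vehicle-only. Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error across regions only. Odds were compared by two-sided Fisher's exact tests across regions, with 0.5 added to each cell for log2 odds ratios, Benjamini-Hochberg adjustment within each family of proteins or lists, and p not written below 1e-300. Regions are not replicates of cells, and neighbouring regions are not independent, so these p-values describe the lists and not the spread between cultures. TRβ T3 regions were placed at random 100 times (seed 1), uniformly along their own chromosomes. Assembly gaps were not excluded, and the distance to gene ends was not matched.

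Gene positions came from a RefSeq table of GRCh38.p14, the same build, which gives start and end of each gene without strand or exons. The planned distance to transcription start sites was therefore replaced by the distance to the nearer annotated gene end, within 1 kb for regions at gene ends and 25 kb for genes near a region. Whether a region is exonic or intronic is not known here. The planned search for sequence motifs was not run, since no genome sequence was used here. The 21 gene lists (442 entries, all matched by symbol) were fixed before the data were examined. Genes named in the text were chosen by a rule fixed at the same time: 9 genes always; up to 4 genes of each list with the highest TRβ T3 signal value within 25 kb; the 10 T3-only, 5 shared and 5 vehicle-only TRβ regions, and the 5 T3-only and 5 vehicle-only regions of each other protein, with the highest signal value, named by the nearest protein-coding gene within 100 kb; and members of lists that passed. Some genes that this rule names are not reported here.

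Alternatives were peaks at an IDR of at most 0.05 or 0.01, lists of equal length, reciprocal 50% overlap, a tolerance of 500 bp, unmerged peaks, the intervals of 1 replicate, gene-end windows of 3 kb, gene windows of 5 and 100 kb, and a background of genes near BRG1 regions. Those added after seeing the data were leaving out regions present in all 8 lists, a limit on the rank difference between replicates, whole gene spans, and Mantel-Haenszel odds ratios within 10-Mb bins or by gene end and region width. Overlap counting was tested on simulated lists with the real number of T3 regions, in which it made 0 wrong calls. In 1000 simulated draws per protein, with the real numbers of T3-only and vehicle-only regions and a planted odds ratio of 2, Fisher's test called 100% of draws, and 5.3% (BRG1), 5.0% (ARID1A) and 4.1% (PBRM1) with no effect. Of simulated gene lists with a raised share, 80% were called over 21 lists, and 0.875% of the unchanged ones. The raised share was 75% against 37% of other genes, as large as in the real list with the highest share. Smaller excesses were not simulated. Both simulations of Fisher's test drew regions or genes independently. Their rates without an effect therefore do not show how often the test over-calls when neighbouring regions are alike. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.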

Results

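The data are CUT&RUN peak lists from Nthy-ORI, an immortalised line of normal human thyroid epithelial cells. CUT&RUN releases the DNA around a bound protein from nuclei with an antibody-directed nuclease. Cells were given T3, the active thyroid hormone, at 10 nM, or vehicle, and the label of each library gives 6 hours, although the protocol text of the labels also names a longer exposure. The antibodies targeted thyroid hormone receptor beta (TRβ), BRG1 (SMARCA4, the ATPase of the BAF and PBAF chromatin remodeling complexes), ARID1A (a subunit of BAF) and PBRM1 (a subunit of PBAF). Each of the 8 combinations of antibody and condition had 2 libraries, and 1 further library was made with IgG, which was not analysed here. Each combination gave 1 list, of peaks found in both libraries, so differences between lists have no replicate check at the level of the list. Read depth is unknown from the lists.

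The lists held 1412 TRβ regions with vehicle and 7208 with T3 on chromosomes 1 to 22, X and Y. For BRG1 the numbers were 64299 and 55938, for ARID1A 49021 and 41710, and for PBRM1 9115 and 38140. The T3 list was therefore 5.10 times as long as the vehicle list for TRβ and 4.18 times as long for PBRM1, whereas it was 0.870 times as long for BRG1 and 0.851 times as long for ARID1A. At an IDR of at most 0.01 the ratio for ARID1A turned to 1.07 (24816 against 23193 regions), and it was 17 for TRβ (3417 against 201), 10.8 for PBRM1 and 0.855 for BRG1. Median region width lay between 669 bp, in the ARID1A vehicle list, and 1249 bp, in the PBRM1 vehicle list. Within the lists, the values of the 2 libraries ranked the regions almost alike for TRβ with vehicle (Spearman rho 0.97 across 1412 regions) and PBRM1 with vehicle (0.90 across 9115), and less alike in the other 6. The rho was -0.03 for TRβ with T3, 0.26 for PBRM1 with T3, 0.48 and 0.47 for BRG1 with vehicle and T3, and 0.16 and 0.21 for ARID1A. These values are across regions, which are not independent replicates. The lists hold only peaks that passed the IDR step, which itself selects for rank agreement between the same 2 libraries. The rho within a list is shaped by that selection and does not measure the quality of the libraries. No peak had identical values in its 2 libraries in any list.

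**Figure D1:**
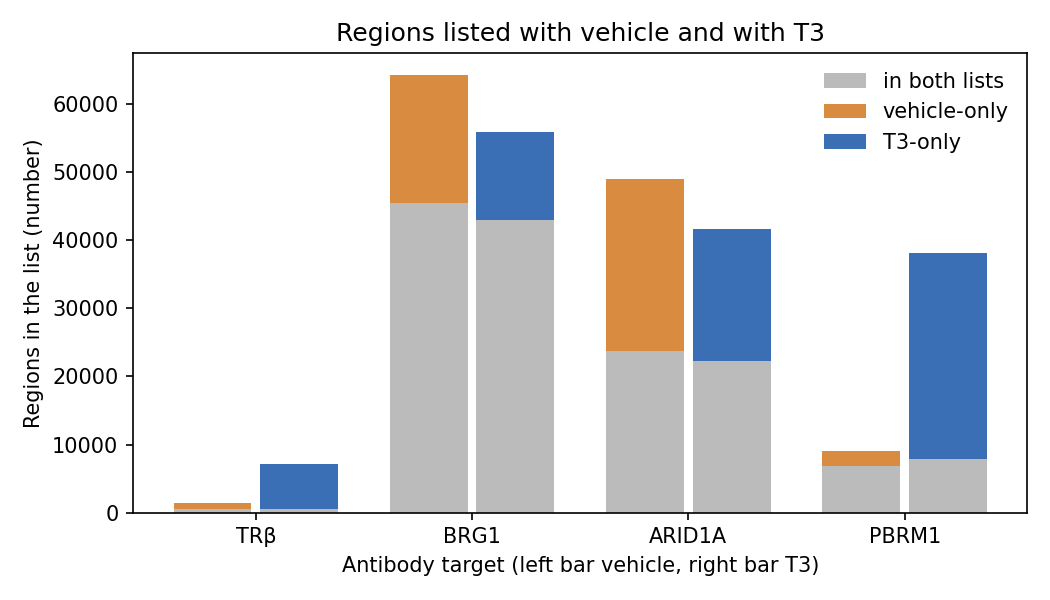
Number of regions in each list (y axis) by antibody target (x axis), with the vehicle list as the left bar and the T3 list as the right bar of each pair; grey marks regions overlapping the other list of the pair, orange vehicle-only and blue T3-only regions. The TRβ and PBRM1 lists were longer with T3 (7208 against 1412 and 38140 against 9115), and the BRG1 and ARID1A lists were shorter, which for ARID1A turned at an IDR of at most 0.01 (24816 against 23193).

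The first comparison asked where the receptor was listed with hormone and without it. Of the 7208 TRβ T3 regions, 6706 (93.0%, exact 95% interval 92.4 to 93.6) had no vehicle region, and 502 overlapped one. Of the 1412 vehicle regions, 947 (67.1%, 64.5 to 69.5) were absent from the T3 list. With each list held to the same number of regions, 81.0% of T3 regions and 81.2% of vehicle regions were in 1 condition only, shares that equal lengths make nearly alike by construction. At an IDR of at most 0.01 the vehicle-only share was 37.8%. The highest-ranked T3-only region lay inside GNG8, which encodes a G-protein gamma subunit, on chromosome 19 (46634031 to 46639742, hg38), with the authors' signal value of 55.2. Others among the first 10 lay inside PRR36 (chromosome 19, 7868383 to 7872429; 42.7), SDR42E2 (chromosome 16, 22189889 to 22192167; 42.0), CELF5 (chromosome 19, 3284312 to 3286573; 39.4), CDKN2D (chromosome 19, 10565642 to 10569455; 37.9), an inhibitor of cyclin-dependent kinases, and KLF13 (chromosome 15, 31326284 to 31327995; 36.0), or outside genes near ZNF846 (chromosome 19, 9791581 to 9793587; 41.3) and FBXL12 (chromosome 19, 9818799 to 9819935; 36.0). A region of 109 bp inside CREBBP, a coactivator gene (chromosome 16, 3849381 to 3849489; 42.9), and one of 10909 bp on chromosome 21 (8436200 to 8447108; 52.2) with no protein-coding gene end within 100 kb completed the 10. These last 2 owed their rank mostly to 1 library, with values of 8.07 and 34.8 for CREBBP and 14.7 and 37.5 on chromosome 21. The GNG8 region had 31.9 and 23.3. Since the 2 libraries ranked TRβ T3 regions with a rho of -0.03, ranks by the summed value need not recur. All 10 regions overlapped BRG1 and ARID1A regions of both conditions. The chromosome 21 region also overlapped PBRM1 regions of both, as some others of the 10 did. The main setting applied no filter for regions that give signal with any antibody.

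The highest-ranked shared TRβ region lay inside STMN3 (chromosome 20, 63641214 to 63642461; signal value 94.7 in the T3 list). It was followed by regions inside GRK1 (chromosome 13, 113724478 to 113727937; 75.6) and ALLC (chromosome 2, 3651320 to 3651441; 66.0), one near CIRBP, which encodes a cold-inducible RNA-binding protein (chromosome 19, 1265085 to 1269863; 45.2), and one inside MNT, a MYC-network repressor gene (chromosome 17, 2395778 to 2402451; 44.6). The ALLC region was 122 bp wide and was present in all 8 lists, in the first place of both ARID1A lists and of the BRG1 vehicle list. Its values in the 2 TRβ T3 libraries were 8.75 and 57.2. The highest-ranked vehicle-only regions lay inside SEMA4C (chromosome 2, 96868534 to 96870556; 29.0 in the vehicle list), MUC5B, a mucin gene (chromosome 11, 1260557 to 1262978; 26.7), TUBGCP2 (chromosome 10, 133294682 to 133296063; 23.5) and LIMK1, a kinase gene of actin regulation (chromosome 7, 74093488 to 74095101; 21.7), and 34.2 kb from an end of ZFP14 (chromosome 19, 36298994 to 36301600; 21.1). The nearest gene ends to the first and the third of these belonged to LOC124908044 and ZNF511.

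Among the remodeler subunits, the T3-only share was lowest for BRG1 and highest for PBRM1. Of the BRG1 T3 regions, 13011 (23.3%, exact 95% interval 22.9 to 23.6) were T3-only, and of the vehicle regions 18821 (29.3%, 28.9 to 29.6) were vehicle-only. For ARID1A the numbers were 19406 (46.5%, 46.0 to 47.0) and 25316 (51.6%, 51.2 to 52.1). For PBRM1 they were 30196 (79.2%, 78.8 to 79.6) and 2268 (24.9%, 24.0 to 25.8), and with lists of equal length 60.6% and 60.7%. The PBRM1 vehicle-only share was 10.9% at an IDR of at most 0.01, and reciprocal overlap of 50% gave BRG1 shares of 49.3% and 55.9%. The 5 highest-ranked PBRM1 T3-only regions lay inside PLEC, which encodes the cytolinker plectin (chromosome 8, 143936407 to 143947660), MEGF6 (chromosome 1, 3540169 to 3549701), SLC9A3, a sodium-proton exchanger gene (chromosome 5, 472048 to 477023), NDST1 (chromosome 5, 150500221 to 150505741) and SHB (chromosome 9, 38023726 to 38029396). Each overlapped BRG1 and ARID1A regions of both conditions, and the first 3 overlapped TRβ regions of both. The 5 highest-ranked PBRM1 vehicle-only regions were nearest to AMOTL2, KLF16, PDGFC, KIRREL1 and ARHGAP17.

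The BRG1 T3-only regions of highest rank were nearest to LAMB1, a laminin gene (chromosome 7, 107997306 to 108000053), MGAT5B, EDN1, which encodes endothelin, BCL2L1, an antiapoptotic gene, and STX16. The vehicle-only ones lay inside GLIS3, a gene of thyroid development (chromosome 9, 4235840 to 4237406), and PDE10A, in both cases over 100 kb from a gene end, and nearest to MED9, TMEM191B and ERBB4. The highest-ranked ARID1A T3-only regions were nearest to CAMTA1, SLC6A3, CFAP46, MVB12B and VWA8, and the vehicle-only ones to CIMAP1B, SBNO2, CHAF1A, RFX2 and ZDHHC20. No region in these 4 sets of BRG1 and ARID1A regions overlapped a TRβ vehicle region, and 2 of the 20, those near CIMAP1B and CHAF1A, overlapped a TRβ T3 region.

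T3-only regions lay less often at gene ends than shared regions for all 4 proteins. The midpoint was within 1 kb of an annotated end of a protein-coding or lncRNA gene in 45.3% of TRβ T3-only regions (3038 of 6706) and 63.5% of shared regions (319 of 502), a log2 odds ratio of -1.07 (SE 0.14; two-sided Fisher's exact test across regions, Benjamini-Hochberg adjusted p = 2.69e-15). The shares were 11.04% and 29.3% for BRG1 (-1.74, SE 0.04), 18.99% and 38.5% for ARID1A (-1.42, SE 0.03) and 31.0% and 48.9% for PBRM1 (-1.09, SE 0.04), with adjusted p of 2e-300, 2e-300 and 3.02e-189 by the same exact test, the first 2 being limited by the smallest p written, 1e-300. Vehicle-only regions also lay at gene ends in lower shares than shared regions, 27.3% for TRβ, 14.3% for BRG1, 14.8% for ARID1A and 17.6% for PBRM1, with no test. For TRβ the difference did not pass with lists of equal length (log2 odds ratio -0.067) or at an IDR of at most 0.01 (-0.44). For PBRM1 it passed but was -0.29 and -0.53 there, and for BRG1 it was -0.93 within 3 kb of a gene end.

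The next comparison asked whether receptor and remodeler were listed at the same places. With T3, 68.2% of TRβ regions overlapped a BRG1 region, 66.3% an ARID1A region and 62.4% a PBRM1 region. Random placements of the TRβ regions on the same chromosomes gave means of 3.97%, 3.06% and 2.74%, and the highest of the 100 placements gave 4.54%, 3.51% and 3.25%; the smallest p that they can give is 0.0099. The placements were uniform, whereas 46.6% of TRβ T3 regions lay within 1 kb of a gene end. Lists that both favour gene ends would exceed such placements, so the excess does not show an association particular to these proteins. All 3 proteins were listed with T3 at 53.7% of TRβ T3 regions (3874 of 7208) and none at 24.5% (1764). The shares at TRβ regions shared by both conditions were higher than at T3-only regions, and those at vehicle-only regions were lower. When regions had to overlap reciprocally by 50%, the shares of TRβ T3 regions were 23.6%, 34.0% and 27.7%. BRG1 with T3 was listed at 90.0% of the shared, 66.6% of the T3-only and 34.0% of the vehicle-only regions.

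**Figure D2:**
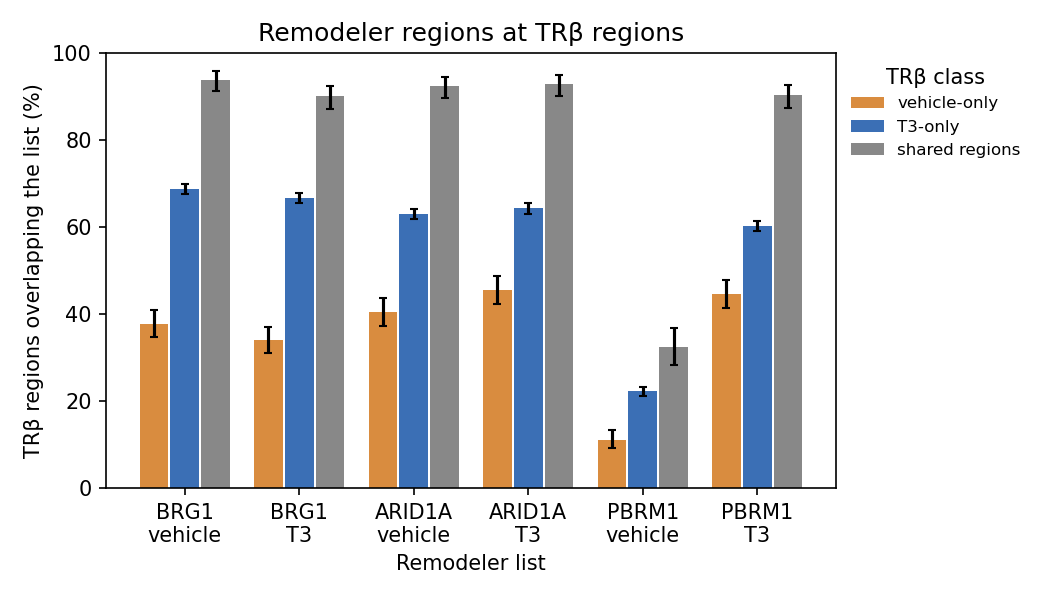
Percentage of TRβ regions (y axis) that overlap each remodeler list (x axis), for vehicle-only (947, orange), T3-only (6706, blue) and shared regions of the T3 list (502, grey); bars are shares and error bars exact 95% binomial intervals. In each of the 6 lists the share was lowest at vehicle-only and highest at shared regions, such as 37.8%, 68.7% and 93.8% for BRG1 with vehicle.

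The vehicle lists of the remodeler subunits were then set against the sites where the receptor was listed only with T3. BRG1 vehicle regions overlapped 68.7% of the TRβ T3-only regions (4610 of 6706) and ARID1A vehicle regions 63.0% (4224), while PBRM1 vehicle regions, of which there were fewer (9115), overlapped 22.2% (1492). When regions had to overlap reciprocally by 50%, the numbers were 1595, 2423 and 528 of 6902. Over the same uniform random placement, with its limits, all TRβ T3 regions overlapped the vehicle lists 16.5-fold (BRG1), 19.8-fold (ARID1A) and 27.8-fold (PBRM1) as often. In TRβ shared regions the shares were 93.8%, 92.4% and 32.5%, which gave log2 odds ratios of -2.77 (SE 0.27), -2.83 (SE 0.24) and -0.75 (SE 0.14) for T3-only against shared regions, with adjusted p of 6.26e-41, 1.89e-49 and 4.85e-07 by two-sided Fisher's exact tests across regions. Of the 6706 TRβ T3-only regions, 64.9% had BRG1 in both lists, 3.88% in the vehicle list only and 1.74% in the T3 list only. PBRM1 was in both lists at 20.9% and in the T3 list only at 39.4%. With lists of equal length the BRG1 difference did not pass (-0.88), the PBRM1 difference turned to 0.15 without passing and the ARID1A difference was -1.11. Without regions present in all 8 lists, a setting that removes shared TRβ regions at PBRM1 vehicle regions, the PBRM1 difference was 2.69.

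Remodeler regions listed in 1 condition only were then compared at TRβ T3 sites. PBRM1 T3-only regions overlapped a TRβ T3 region in 9.64% (2910 of 30196) and vehicle-only regions in 3.40% (77 of 2268), a log2 odds ratio of 1.59 (SE 0.17; adjusted p = 2.83e-28 by two-sided Fisher's exact test). For ARID1A the shares were 2.91% and 2.10% (0.48, SE 0.09; adjusted p = 8.03e-08, same exact test). For BRG1 the order was opposite, with 0.991% and 1.57% (-0.67, SE 0.15; adjusted p = 8.94e-06, same exact test). When regions had to overlap reciprocally by 50%, the ARID1A and BRG1 differences did not pass (0.11 and 0.13) and the PBRM1 difference was 0.59, while at an IDR of at most 0.01 it was 0.83. A limit on the rank difference between the 2 libraries was set per protein, at what 95% of its vehicle regions met. It was 13.5% of the list length for TRβ, 25.4% for PBRM1, 58.6% for BRG1 and 72.3% for ARID1A. Under it 1864 of the 7208 TRβ T3 regions were kept, and the PBRM1 and BRG1 differences did not pass (0.042 and -0.43). At TRβ vehicle regions, of which 465 overlapped a TRβ T3 region, the T3-only and vehicle-only shares ran in the same orders, without a test. They were 2.19% and 0.66% for PBRM1, 0.90% and 0.57% for ARID1A, and 0.17% and 0.45% for BRG1. The orders alone therefore do not set TRβ T3 regions apart.

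**Figure D3:**
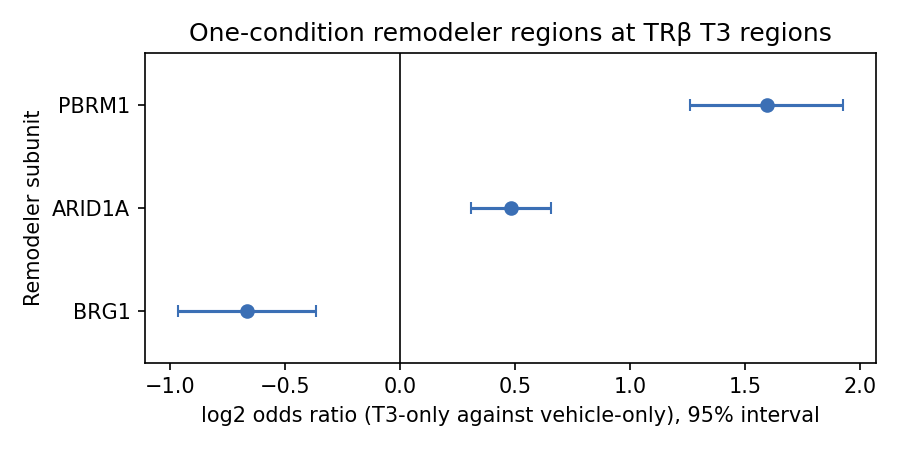
Log2 odds ratio (x axis) of overlapping a TRβ T3 region, for T3-only against vehicle-only regions of each remodeler subunit (y axis), as points with 95% intervals across regions; the vertical line marks no difference. PBRM1 (1.59) and ARID1A (0.48) lay above 0 and BRG1 (-0.67) below it. The shares at TRβ vehicle regions, not drawn, ran in the same orders.

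BRG1 regions were then divided by the subunits listed with them. With vehicle, 8.84% of the 64299 BRG1 regions overlapped both ARID1A and PBRM1, 29.3% ARID1A alone, 4.11% PBRM1 alone and 57.7% neither. With T3 the shares of 55938 regions were 28.2%, 15.4%, 11.04% and 45.4%, with no test between conditions, whose PBRM1 lists differed 4.18 times in length. At TRβ T3 sites, 80.6% of BRG1 T3 regions (3830 of 4750) overlapped both subunits, against 23.3% (11942 of 51188) elsewhere, a log2 odds ratio of 3.77 (SE 0.06; two-sided Fisher's exact test, p at the smallest value written, 1e-300). With vehicle the shares at the same sites and elsewhere were 32.0% (1567 of 4892) and 6.93% (4114 of 59407), not tested. Over 10 alternative settings the log2 odds ratio with T3 ran from 2.67 to 3.83. It was not stratified by region width, although wider regions meet the 1 bp rule more easily. Signal value and width of BRG1 T3 regions rose together (Spearman rho 0.84 across regions), so a part of width or strength in the contrast stays open.

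Of 20033 protein-coding genes, 7499 (37.4%) had a TRβ T3 region within 25 kb of an annotated end. Neighbouring genes could share a region, such as CDKN2A and CDKN2B in the cell cycle list, whereas the tests below treat genes as independent. Of 21 lists fixed before the data were examined, 7 held more such genes than the remaining genes did (two-sided Fisher's exact tests, Benjamini-Hochberg over the lists). In the hypoxia and glycolysis list 15 of 20 genes had one (log2 odds ratio 2.24, SE 0.72; exact test, adjusted p = 0.00681). They included the glycolytic enzyme genes ENO1 (chromosome 1, 8877905 to 8879638; signal value 24.0) and PKM (chromosome 15, 72230160 to 72231752; 16.1), BNIP3, a mitophagy gene (chromosome 10, 131980911 to 131982527; 20.8), and EPAS1, which encodes a hypoxia-inducible factor (chromosome 2, 46297115 to 46298317; 14.8). These 4 regions were T3-only. In the cell cycle list 17 of 23 genes had one (2.17, SE 0.66; exact test, adjusted p = 0.00681), with CCNE1, CCNE2, E2F1 and E2F2, cyclin E and E2F genes, ranking first. In the list of SWI/SNF subunit genes it was 19 of 27 (1.94, SE 0.59; exact test, adjusted p = 0.00681), led by BCL7B, SMARCD3, ARID1A and PBRM1.

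The other 4 lists that passed the exact test were AP-1 and related bZIP factors (13 of 18; log2 odds ratio 2.04, adjusted p = 0.0190), receptor kinase, RAS-MAPK and PI3K genes (18 of 26; 1.87, adjusted p = 0.00875), lipid and cholesterol metabolism (14 of 20; 1.90, adjusted p = 0.0179) and TGF-beta, mesenchymal and matrix genes (14 of 22; 1.51, adjusted p = 0.0435). FOSB (chromosome 19, 45467700 to 45470520; signal value 34.1), JUND, FOSL2 and ATF3 led the AP-1 list. IGF1R and AKT1 led the kinase list. NR1H2, a liver X receptor gene, INSIG1, ACLY and FASN led the lipid list, and COL1A1, VIM and SMAD7 were among the first of the TGF-beta list. Against protein-coding genes with a BRG1 region nearby, 0 of the 21 lists passed Fisher's exact test (6 at an unadjusted p under 0.05), with an adjusted p of 0.0567 for the cell cycle and for the hypoxia list. By the same exact test 3 of the 7 lists passed at an IDR of at most 0.01 (SWI/SNF, AP-1 and kinase), where the hepatocyte list passed with fewer genes than expected (0 of 20, log2 odds ratio -3.73). With lists of equal length 2 of the 7 passed (SWI/SNF and AP-1). With a window of 100 kb 0 of the 21 lists passed (4 unadjusted, 1 of them with fewer genes). Under the limit on rank difference, which kept 1864 of the 7208 TRβ T3 regions, 0 passed (3 unadjusted). The log2 odds ratios of the 7 lists, 1.51 to 2.24 with all genes as background, were 1.10 to 2.12 against genes near BRG1 regions, 0.58 to 2.24 at the stricter IDR, 0.18 to 2.66 with equal lengths, 0.85 to 1.47 with 100 kb and 0.41 to 1.67 with the rank limit. Some lost calls kept much of their size, such as the cell cycle list with equal lengths (1.79), and others did not, such as the kinase list there (0.33).

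**Figure D4:**
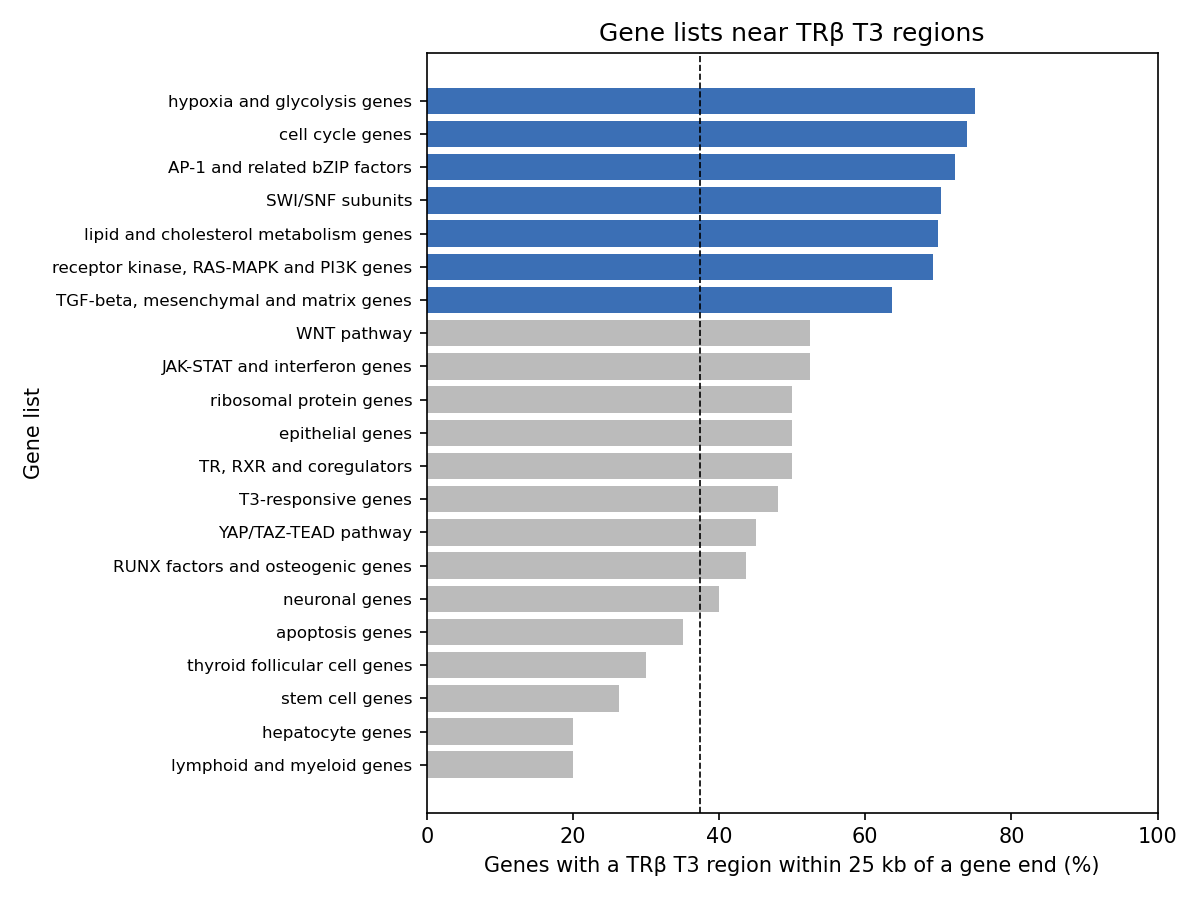
Percentage of the genes of each list (y axis) with a TRβ T3 region within 25 kb of an annotated gene end (x axis); blue bars passed the test at an adjusted p under 0.05, grey bars did not, and the dashed line marks 37.4% of all protein-coding genes. Shares ran from 20% in the hepatocyte and the lymphoid and myeloid lists to 75% in the hypoxia and glycolysis list.

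The other 14 lists did not pass, and how often an excess smaller than the simulated one would pass is not known. T3-responsive genes had a TRβ T3 region in 12 of 25 cases (log2 odds ratio 0.63, SE 0.57; exact test, adjusted p = 0.425), with ANGPTL4, FASN and SLC2A4 ranking first; the ANGPTL4 region was shared with the vehicle list. Receptors and coregulators had one in 10 of 20 (CARM1, RXRB, GPS2 and MED1 first), thyroid follicular cell genes in 6 of 20 (HHEX, PAX8, DUOX1 and DUOX2 first), and the lists of other cell types in 8 of 20 (neuronal), 4 of 20 (lymphoid and myeloid) and 4 of 20 (hepatocyte). Of the 6 thyroid genes, DUOX2, DUOXA1 and DUOXA2 had only 1 region, the same for each, and lie beside DUOX1 on chromosome 15. In the remaining lists the highest-ranked regions lay near TEAD2 (YAP/TAZ-TEAD), CLDN7 (epithelial), FZD7 (WNT), IRF7 and IRF9 (interferon), CASP9 and BBC3 (apoptosis), NOTCH1 (stem cell), ATF4 (RUNX and osteogenic) and RPL18 (ribosomal protein). The CLDN7 region was the SLC2A4 region named above, 18.2 kb from an end of CLDN7 and 0.257 kb from one of SLC2A4. The counts were 9 of 20 for YAP/TAZ-TEAD, 10 of 20 for epithelial, 11 of 21 for WNT, 11 of 21 for JAK-STAT and interferon, 7 of 20 for apoptosis, 5 of 19 for stem cell, 7 of 16 for RUNX and osteogenic, and 12 of 24 for ribosomal protein genes. For regions of BRG1, ARID1A or PBRM1 listed in 1 condition only, 0 of the 21 lists differed from other genes in the balance of T3-only and vehicle-only regions by Fisher's exact test after adjustment. At an unadjusted p under 0.05 there were 1 list for BRG1, 2 for ARID1A and 0 for PBRM1. With lists of equal length 1 list passed for PBRM1, and with a window of 100 kb 2 passed for ARID1A.

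Among genes named in advance, THRA (TRα), RXRA, KLF9, a known T3 target, and PBRM1 had a TRβ region within 25 kb with T3 and not with vehicle, and regions of the 3 remodeler subunits in both conditions. Of all protein-coding genes, 37.4% had a TRβ region within 25 kb with T3 and 10.4% with vehicle, so this state is not particular to these genes. THRB itself had remodeler regions of all 6 lists and no TRβ region. SMARCA4 had a TRβ T3 region 0.018 kb from its annotated end and lacked PBRM1 with vehicle. ARID1A and PAX8, a thyroid transcription factor gene, had regions of all 8 lists, although the strongest TRβ T3 region near each was T3-only. RUNX2 had a TRβ region with T3, 22.6 kb from an end (chromosome 6, 45305517 to 45305929), and no remodeler region within 25 kb in any list. By signal value this TRβ region ranked 6863 of 7208.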

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

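The tests of rank agreement between replicates and of segments shared by antibodies, the odds within 10-Mb bins, and the differences between proteins under other settings, were chosen only after the results they bear on were seen. The other tests were set before their values were seen, on patterns found in the same data.

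The odds of T3-only at TRβ T3 sites differed between proteins in the main setting, though not in every other. By a two-sided z-test of the difference of log2 odds ratios across regions, which are not replicates, PBRM1 exceeded BRG1 by 2.26 (SE 0.23), ARID1A exceeded BRG1 by 1.15 (SE 0.18) and PBRM1 exceeded ARID1A by 1.11 (SE 0.19), with adjusted p of 1.17e-22, 1.18e-10 and 5.82e-09. At reciprocal 50% overlap the 3 differences were 0.47, -0.020 and 0.49 (adjusted p 0.0123, 0.879 and 0.00593), and under the limit on rank difference 0.47, 0.82 and -0.35 (0.0993, 0.0127 and 0.0993). At an IDR of at most 0.01 PBRM1 and ARID1A differed by 0.36 (adjusted p 0.394). These differences were tested at TRβ T3 sites only, and the shares at TRβ vehicle regions ran in the same orders. Peaks on contigs outside the main chromosomes entered no comparison. They numbered 25 and 75 for TRβ with vehicle and T3, 94 and 63 for BRG1, 246 and 203 for ARID1A, and 9 and 102 for PBRM1.

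The TRβ and PBRM1 lists were far shorter with vehicle than with T3. A lower depth or yield of the vehicle libraries would lose weak regions first, and the share of T3 regions missing from the vehicle list did fall, from 97.5% in the decile of lowest signal values for TRβ and 91.7% for PBRM1. In the decile of highest values 74.6% (exact 95% interval 71.3 to 77.8) were still missing for TRβ and 53.0% (51.4 to 54.6) for PBRM1. The missing regions were therefore not confined to low signal values. The rule set beforehand was whether most of that decile was missing, which such a loss does not forbid. Signal value may also measure strength poorly, as the 2 T3 libraries ranked regions with a rho of -0.03 for TRβ and 0.26 for PBRM1. With read depth unknown, the test cannot decide how much such a loss contributed. Both short lists had the highest agreement between their libraries, and a stricter demand on rank agreement in the IDR step is a candidate explanation; under the rank-difference limit that 95% of vehicle regions met, the T3 list was 1.39 times as long as the vehicle list for TRβ and 2.31 times for PBRM1, which leaves it open, since vehicle peaks that failed the IDR step are not in the lists. A hormone effect on binding stays open as well, because condition and list coincide.

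The balance of ARID1A T3-only and vehicle-only regions differed along the genome, on the autosomes from 1346 against 807 on chromosome 20 to 184 against 498 on chromosome 18. Neighbouring 10-Mb bins resembled each other (Spearman rho 0.59 across bins). Gene density, a stand-in for base composition, gave a rho of 0.17 over 291 bins, too low to account for the balance and, given its spread, too high to exclude a part in it. Segments that differ between the vehicle and T3 cells or libraries whatever the antibody, copy number being an untested example, may contribute. The balance per bin correlated with that of BRG1 (0.43) and of PBRM1 (0.28). BRG1 shares a complex with ARID1A and with PBRM1, and TRβ was not compared in this way. The correlations therefore cannot tell such segments from a joint difference in remodeler binding. Within bins the log2 odds ratios at TRβ T3 regions were -0.52 for BRG1, 0.48 for ARID1A and 1.56 for PBRM1. No biological explanation of the segments was tested.

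TRβ vehicle-only regions lay at remodeler regions less often than shared regions did. A region of any remodeler list was present at 64.1% of them and at 98.3% of shared vehicle regions, a log2 odds ratio of 4.91. Low rank near the limit of detection was not the whole cause, as the log2 odds ratio within deciles of vehicle signal was 3.88 (95% interval 2.84 to 4.92). Without regions present in all 8 lists the log2 odds ratio was 4.44 (3.44 to 5.44). That filter removed 132 TRβ vehicle regions and depends on the short PBRM1 vehicle list. Of the 465 shared vehicle regions, 31.4% lay at PBRM1 vehicle regions and 90.3% at PBRM1 T3 regions. Many regions listed with every antibody in 1 condition therefore stayed in, and regions that do not depend on the antibody are not excluded as a cause. A different kind of site without hormone stays open as well and was not tested.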

How the results depend on the processing

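Leaving out regions present in all 8 lists, the rank limit, whole gene spans and the stratified odds ratios were chosen after seeing the data; where a value moved, the cause was not tested unless stated. No paired analysis was possible because each group had 1 merged list and the columns carry no replicate numbers. The motif alternatives were not run. An IDR of at most 0.05 and unmerged peaks left every value as it was, by construction, and a gene-end window of 3 kb, whole gene spans and the stratified odds ratios changed no call. A gene window of 5 kb changed 1, with the WNT list passing and 8 lists in all. Read depth is not known, so its limit on the short lists cannot be stated.

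In the order TRβ T3-only, vehicle-only, then the same for BRG1, ARID1A and PBRM1, the shares were 95.9%, 37.8%, 19.1%, 26.8%, 48.8%, 43.4%, 89.9% and 10.9% at an IDR of at most 0.01; 81.0%, 81.2%, 26.3%, 24.2%, 49.4%, 47.2%, 60.6% and 60.7% with lists of equal length; and 95.8%, 78.3%, 49.3%, 55.9%, 66.3%, 71.3%, 87.0% and 45.5% at reciprocal 50% overlap. With 500 bp counted as shared, the TRβ T3-only share was 92.0%, and the BRG1, ARID1A and PBRM1 shares were 15.6%, 21.7%, 40.0%, 45.3%, 75.2% and 19.9%. Without regions present in all 8 lists the TRβ shares were 95.1% and 74.1%. Under the limit on rank difference the 8 shares were 89.5%, 85.7%, 26.5%, 32.4%, 48.8%, 53.4%, 77.8% and 51.9%.

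The overlap of TRβ T3 regions with BRG1, ARID1A and PBRM1 was 80.4%, 76.3% and 70.1% at an IDR of at most 0.01; 94.5%, 95.5% and 59.1% with equal lengths; 23.6%, 34.0% and 27.7% at reciprocal overlap; 70.3%, 69.8% and 65.8% with 500 bp; 66.7%, 65.1% and 61.1% without regions present in all lists; and 70.8%, 69.1% and 43.7% under the rank limit.

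With the intervals of 1 replicate alone, T3-only and vehicle-only shares were 24.6% to 24.8% and 30.6% to 30.9% for BRG1, 47.4% to 47.9% and 52.5% to 53.0% for ARID1A, 79.4% to 79.7% and 25.3% to 25.9% for PBRM1, and the overlap of TRβ T3 regions was 65.0% to 65.5% with ARID1A and 60.6% to 61.6% with PBRM1; no call changed.

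The TRβ gene-end log2 odds ratio lost its call at an IDR of at most 0.01 (-0.44) and with equal lengths (-0.067). With equal lengths the log2 odds ratio of BRG1 in vehicle at TRβ T3-only regions was -0.88 and that of PBRM1 turned to 0.15. PBRM1 there was 2.69 without regions present in all lists, a setting that by construction removes shared TRβ regions at PBRM1 vehicle regions. At reciprocal overlap the log2 odds ratios of T3-only at TRβ T3 regions turned to 0.13 for BRG1 and fell short at 0.11 for ARID1A. Under the rank limit they were -0.43 for BRG1 and 0.042 for PBRM1. The number of lists that passed near TRβ T3 regions was 4 at an IDR of at most 0.01 (3 of the main 7, and the hepatocyte list with fewer genes than expected), 2 with equal lengths, 0 with a window of 100 kb, 0 against genes near BRG1 regions and 0 under the rank limit (main 7). The number near one-condition regions was 1 for PBRM1 with equal lengths and 2 for ARID1A at 100 kb (main 0 and 0). Lists with a replicate rho below 0.5 numbered 2 under the rank limit, which selects for agreement (main 6).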

Other observations

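No test in this part was chosen only after its result was seen, but the lists described first were picked for their low unadjusted p. Genes of AP-1 and related bZIP factors, which respond to stress and growth signals, did not differ from other genes after adjustment in the balance of remodeler regions listed in 1 condition only. For ARID1A there were 47 T3-only and 32 vehicle-only regions within 25 kb of these genes, against 12813 and 15393 near other genes (log2 odds ratio 0.81, SE 0.33; two-sided Fisher's exact test, p = 0.0128, adjusted p = 0.135 over 21 lists). For BRG1 there were 41 and 32, against 7485 and 11450 (0.97, SE 0.34; same exact test, p = 0.00544, adjusted p = 0.114). Near genes of thyroid hormone receptors, retinoid X receptors and coregulators there were 55 T3-only and 39 vehicle-only ARID1A regions (0.76, SE 0.30; same exact test, p = 0.0125, adjusted p = 0.135).

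Of all protein-coding genes, 81.6% had a BRG1 region within 25 kb with vehicle and 78.6% with T3, and 42.1% and 76.9% a PBRM1 region; presence was not tested between lists, and the lists named next were picked after their values were seen. All 27 SWI/SNF subunit genes had a BRG1 region within 25 kb in both conditions and a PBRM1 region with T3, and 16 had a PBRM1 region with vehicle. BRG1 regions were near every gene in both conditions in other lists too, among them the YAP/TAZ-TEAD, epithelial, apoptosis, lipid and ribosomal protein lists. All 23 cell cycle genes had BRG1 and ARID1A regions in both conditions, and 13 had a PBRM1 region with vehicle. Of the 20 hepatocyte genes, which serve as genes of another cell type, 10 had a BRG1 region with vehicle and 12 with T3, and 3 had a PBRM1 region with vehicle and 10 with T3.

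The hypothesis that TRβ vehicle regions do not depend on the antibody was tested with lists of equal length. Of the 1412 TRβ vehicle regions, 32.9% (exact 95% interval 30.5 to 35.5) overlapped the TRβ T3 list of 7208 regions. The 7208 PBRM1 T3 regions with the highest signal values overlapped 30.0% (27.6 to 32.5), those of ARID1A 29.8% and those of BRG1 21.7%. The intervals for TRβ and PBRM1 overlap, so that TRβ vehicle regions may lie as often at the strongest PBRM1 regions as at TRβ T3 regions, and the hypothesis was neither excluded nor borne out. The regions covered 5.81 Mb for TRβ, 13.5 Mb for PBRM1, 11.7 Mb for ARID1A and 21.0 Mb for BRG1. BRG1 covered the most and had the lowest overlap. PBRM1 and ARID1A also covered more than TRβ, and wider regions meet the 1 bp rule more easily, so a part of covered length stays open.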
